A study of Mus musculus with 4 samples.

How the data were processed

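RNA was extracted with TRIzol from cultured newborn mouse cardiac fibroblasts, ribosomal RNA was depleted, and stranded libraries were sequenced as paired reads, per the labels' protocols. The labels name the molecule as polyA RNA, although the kit named depletes ribosomal RNA. The authors deposited a table of whole-number counts per Ensembl gene for the 4 libraries, per the file headers. Per the submitters' processing notes, Trimmomatic 0.36, Subread 1.5.1, featureCounts, SAMtools and the build mm10 were used. The aligner, the annotation release and the strand setting are not given in the sources used here. The same table holds 4 per-sample columns of FPKM, which were not used here, and the exonic length of each gene, taken as deposited. The gene coordinates in the table matched those of GENCODE M21 on GRCm38 in start and end for only 1494 of 52083 shared identifiers, so coordinates are printed from GENCODE M21, matched by Ensembl identifier. Genes that share reads with near-identical copies, such as ribosomal protein genes and some mitochondrial genes, have uncertain counts.

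Samples were grouped by the sample titles, with 2 OECtrl and 2 OENr4a3 libraries. Between replicates, the chi-square over its degrees of freedom was 17.0 in OECtrl (14571 genes) and 2.64 in OENr4a3 (14837 genes), so neither pair agreed within sampling noise and all 4 libraries were kept. Pearson correlations of log2 CPM were 0.9862 within OECtrl, 0.9928 within OENr4a3 and 0.9592 to 0.9733 between groups, across 15029 genes.

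Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM (factors 1.014, 1.017, 0.9857 and 0.9842), and OENr4a3 was compared with OECtrl by the quasi-likelihood F-test (glmQLFit, glmQLFTest), two-sided, without a replicate block. The biological coefficient of variation was 0.0955. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. Standard errors are the log2 fold change over the square root of F, and 95% intervals use the fit's degrees of freedom. Levels are CPM on TMM-scaled library sizes, with the SD over 2 libraries. Ratios of genes with 3 reads or fewer in a group have exact binomial (Clopper-Pearson) 95% counting intervals over the summed reads. Such intervals, and the floor of 3 reads, cover counting error only.

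The design, the 25 gene lists (8 on the study's subject and 17 others) and the other settings to be tried were fixed before the data were examined. Lists were tested by camera with a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 25 lists, and again with an estimated correlation and with fry. Camera called 9 lists. With an estimated correlation limma's camera called 0, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.599. It rests on the few residual degrees of freedom of 4 libraries in 2 groups. It thus had little power, and failing it does not decide whether a list moved. Fry called 0, with 9 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0644.

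Named genes followed a rule fixed at the same time. It takes Nr4a3, Nr4a1 and Nr4a2; Mef2c, Gata4 and Tbx5; the 5 largest rises and 5 largest falls among called genes with a mean over the 4 libraries of at least 5 CPM and no overlap between the groups, leaving out predicted and unnamed genes; the 3 members with the smallest p in each study list; the 2 such members of each other list past camera; and the most abundant marker of each cell type list. Other genes are named as chosen after their values were seen.

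The pipeline was tested on simulated counts made from the means and library sizes of OENr4a3 and OECtrl, with 14739 genes tested. It called 30.9% of 68 genes changed 1.5-fold, 72.3% of 65 changed 2-fold and 96.9% of 65 changed 4-fold, and 6.85% of its 146 calls were unchanged genes. It called the list that was moved and 0 of 24 that were not. Simulated genes were drawn independently and without a length trend. The result therefore does not cover false calls of lists whose members vary together, such as oxidative phosphorylation (estimated correlation 0.781).

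The alternatives were DESeq2, limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a filter of 1 CPM in 2 libraries, leaving out each library in turn, a replicate block, stricter thresholds, and lists without shared members. Added after seeing the data were a removal of the trend of log2 CPM with exonic length from each library (lowess, span 0.3), the same with GC content of GENCODE M21 transcripts, and an enrichment of the deposited Gene Ontology terms of 10 to 500 genes by the one-sided Fisher's exact test. On simulated counts with an added length trend, the removal took Spearman's rho with length from 0.722 to 0.0224 (14800 genes). Leaving out a library leaves a group with 1 library, which is then assumed to vary like the other group. A call lost or gained in such a fit can thus reflect which pair set the spread, and not the library left out.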

Results

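Cardiac fibroblasts, the matrix-producing cells of the heart, were grown as primary cultures from wild-type newborn mice and made to overexpress Nr4a3 (OENr4a3) or an overexpression control (OECtrl). Nr4a3 is an orphan nuclear receptor of the NR4A family. The stated purpose was to find how Nr4a3 affects direct reprogramming of fibroblasts into induced cardiomyocytes, and the series title links Nr4a3 to senescence. Polyadenylated or ribosomal RNA-depleted RNA was measured by sequencing in 4 libraries, 2 per group. The sample titles give day 10, whereas the design text gives reprogramming day 7, so the time point stays open. The libraries held 14275501 and 16461333 counts in OECtrl and 18441428 and 18287644 in OENr4a3. At these depths a count of 0 allowed up to 3 reads, or 0.165 to 0.208 CPM (counts scaled to library size), counting error only. No label says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Of 55359 genes listed, 27419 had a read and 15029 passed the filter on low counts.

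Nr4a3 itself rose from 2.17 ± 0.45 CPM in OECtrl to 176.6 ± 1.72 CPM in OENr4a3 (SD, n = 2 each), an 81.7-fold difference (log2 fold change 6.35 ± 0.158 SE, adjusted p = 1.13e-07). The OECtrl libraries held 36 and 31 Nr4a3 reads and the OENr4a3 libraries 3184 and 3196. The counts do not separate transcripts of the introduced copy from those of the gene on chromosome 4 (48045153 to 48086447, plus strand, GRCm38; ENSMUSG00000028341). Of its relatives, Nr4a1 fell from 17.8 ± 0.0306 to 12.1 ± 1.25 CPM (log2 fold change -0.55 ± 0.144 SE, adjusted p = 0.0254), and Nr4a2 stood at 1.355 and 2.242 CPM without passing the test (log2 fold change 0.73, adjusted p = 0.131). The Nr4a1 call was lost without OENr4a3 replicate 1 (adjusted p = 0.0878) or replicate 2 (0.29) and without the filter on low counts (0.062).

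The factors most used for direct cardiac reprogramming did not pass the test. Mef2c measured 22.5 ± 1.95 CPM in OECtrl and 27.8 ± 0.0382 in OENr4a3 (log2 fold change 0.31, 95% interval 0.0256 to 0.593, adjusted p = 0.102). Gata4 measured 169.9 ± 0.509 and 184.8 ± 5.49 CPM (log2 fold change 0.12, interval -0.0925 to 0.335, adjusted p = 0.375). Tbx5 was scarce, at 1.53 ± 0.475 and 2.55 ± 0.409 CPM (log2 fold change 0.74, interval -0.028 to 1.52, adjusted p = 0.14). Without OECtrl replicate 1, where the spread came from the closer OENr4a3 pair, Mef2c and Tbx5 passed as higher in OENr4a3. With the trend with gene length removed, a test added after seeing the data, Mef2c stood at -0.12 (adjusted p = 0.487).

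**Figure D1:**
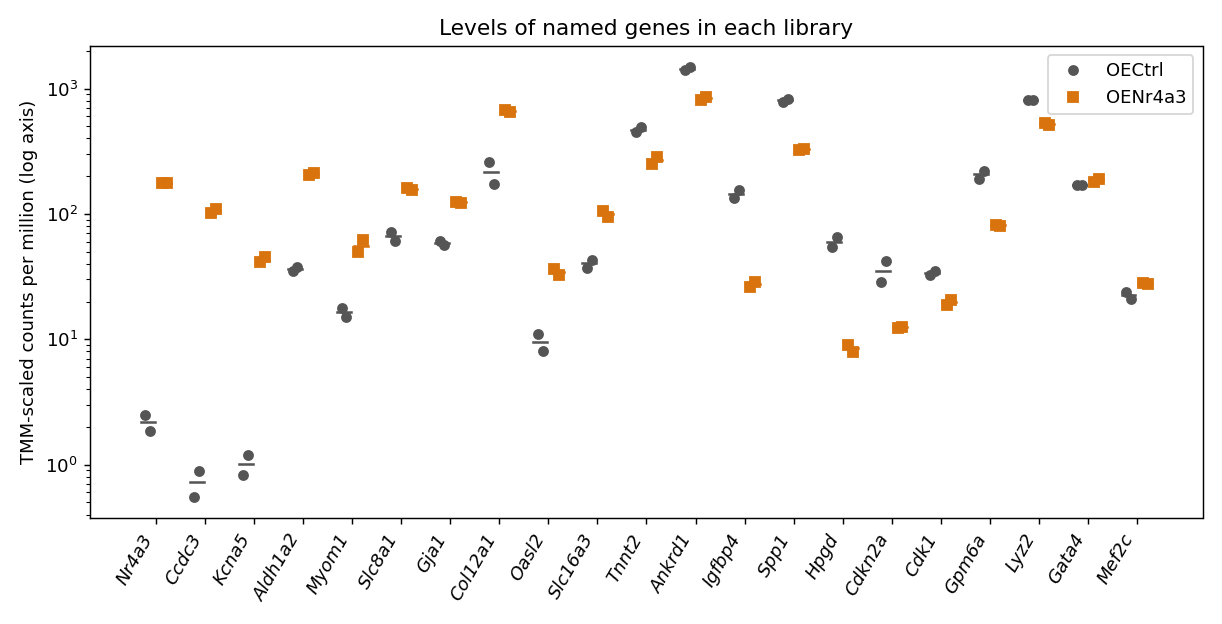
Normalised level of 21 named genes in each library, in TMM-scaled CPM on a log axis; circles are OECtrl and squares OENr4a3 libraries, with a short line at each group mean (n = 2). Nr4a3 lies near 2.17 CPM in OECtrl and 176.6 CPM in OENr4a3, and the libraries of Gata4 and Mef2c lie close together between groups.

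Across the transcriptome, 3457 of 15029 tested genes (23.0%) differed between OENr4a3 and OECtrl in edgeR's quasi-likelihood test at an adjusted p of 0.05. Of these 1802 were higher and 1655 lower in OENr4a3, with a median absolute log2 fold change of 0.64, and 452 and 351 of them moved at least 2-fold. The largest rises under the naming rule were in Rln3, which encodes the peptide hormone relaxin-3, in Tub, in Ccdc3, in Nr4a3 and in Kcna5, which encodes a voltage-gated potassium channel. Rln3 went from 2 reads in both OECtrl libraries together to 2272 in OENr4a3, a ratio of 980 (95% counting interval 271 to 8100). Tub went from 2 to 599 reads, a ratio of 258 (71.2 to 2140), and its fitted log2 fold change of 7.86 became 11.19 without OECtrl replicate 1, which held both OECtrl reads, and 6.83 without replicate 2. Ccdc3 rose from 0.726 ± 0.243 to 105 ± 5.36 CPM (log2 fold change 7.14 ± 0.192 SE, adjusted p = 1.15e-07) and Kcna5 from 1.01 ± 0.259 to 43.2 ± 2.61 CPM (5.39 ± 0.198 SE, adjusted p = 1.07e-06).

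The largest falls were in Alb, Hpgd, Tspan8, Krt8 and Igfbp4. Alb, serum albumin of the liver, had 798 reads in OECtrl and 1 in OENr4a3, a 925-fold ratio (95% counting interval 166 to 36600). Together, 36 liver genes held 2241 and 2137 reads in OECtrl and 518 and 471 in OENr4a3; without Trf, the most abundant, they held 1423 and 1251 against 89 and 59. Whether the Alb reads of OECtrl came from the fibroblasts was not determined, so the ratio describes the libraries. Hpgd, the prostaglandin-degrading dehydrogenase, fell from 59.99 ± 7.63 to 8.47 ± 0.801 CPM (log2 fold change -2.82 ± 0.147 SE, adjusted p = 1.05e-05). Igfbp4, a binding protein of insulin-like growth factors, fell from 144.3 ± 13.5 to 27.5 ± 1.92 CPM (-2.39 ± 0.12 SE, adjusted p = 9.64e-06). The tetraspanin Tspan8 (-2.77 ± 0.373 SE, adjusted p = 0.0018) and the keratin Krt8 (-2.40 ± 0.324 SE, adjusted p = 0.00184) also fell. Log2 fold changes of these 10 genes kept their sign and side of the threshold under all 13 alternative fits that gave a gene-level value, but some moved in size. Without OENr4a3 replicate 1 or 2, Tspan8 stood at -3.81 and -2.18, and Alb at -11.73 and -8.69 against -9.53 with all libraries.

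The number of called genes depended on the libraries, with fewer calls without either OENr4a3 library and more without either OECtrl library. Each such fit has 1 library in a group and takes its spread from the other pair, which differed more in OECtrl. Testing every gene with a read left 1878 calls, 59.7% of them higher against 52.1% in the main count.

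In GRCm38, Rln3 (ENSMUSG00000045232) lies on chromosome 8 from 84042929 to 84045000, minus strand, and Kcna5 (ENSMUSG00000045534) on chromosome 6 from 126532551 to 126535412, minus strand. Tub (ENSMUSG00000031028) spans 108950338 to 109034460 on the plus strand of chromosome 7 and overlaps Ric3 and Gm26599 on the other strand. Ccdc3 (ENSMUSG00000026676) spans 5137776 to 5230878 on the plus strand of chromosome 2 and overlaps Gm13198 on its own strand and Gm26776 on the other. Alb (ENSMUSG00000029368) lies on chromosome 5 from 90460897 to 90476602, plus strand, and Igfbp4 (ENSMUSG00000017493) on chromosome 11 from 99041244 to 99054392, plus strand. Hpgd (ENSMUSG00000031613) spans 56294585 to 56321043 on the plus strand of chromosome 8 and overlaps Gm45540. Because the strand setting of the counting is not given in the sources used here, reads of overlapping genes cannot be told apart.

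Those sarcomere genes that were abundant enough to test moved both ways. Members below the filter included Myh7 (0 and 0 reads in OECtrl, 5 and 2 in OENr4a3), Tnni3 (6 and 5, 5 and 5), Myl2 (1 and 1, 3 and 4) and Actn2 (3 and 0, 12 and 6). Of 30 sarcomere genes, the contractile apparatus of heart muscle, 18 were tested, 6 rose and 5 fell (8 and 6 adjusted over the list alone), and the list did not pass the competitive camera test (median log2 fold change 0.09, adjusted p = 0.727). Myom1, the M-band protein myomesin, rose from 16.5 ± 2.06 to 55.6 ± 8.85 CPM (log2 fold change 1.76, adjusted p = 0.000195). Tnnt2, cardiac troponin T, fell from 471.3 ± 33.5 to 267 ± 23.8 CPM (-0.82, adjusted p = 0.0014), and Ankrd1 fell from 1441 ± 49 to 840.7 ± 32.1 CPM (-0.78, adjusted p = 0.000717). Picked after their values were seen, the other members that fell were Cryab, Myl4 and Tpm1, and those that rose were Myh6, Ttn, Nebl, Smpx and Myom2, each below 10 CPM in both groups. Myh6, the alpha myosin heavy chain of heart muscle, measured 0.687 ± 0.887 and 4.20 ± 1.77 CPM. Its log2 fold change of 2.68 became 5.98 without OECtrl replicate 1 and 1.67 without replicate 2, and its call was lost in DESeq2 (adjusted p = 0.273) and without the filter on low counts (0.0572). The calls of Tpm1 (adjusted p = 0.294 and 0.271) and Ttn (0.056 and 0.111) were lost without OENr4a3 replicate 1 or 2, that of Myom2 without replicate 1 (0.308) and that of Myl4 without replicate 2 (0.0569), and Myl4 went from -0.73 to -0.48 without OECtrl replicate 2. With the length trend removed, the calls of Ttn (0.66, adjusted p = 0.295) and Myom2 (0.45, adjusted p = 0.118) were lost, and Cryab stood at -0.43.

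Of 29 cardiac ion handling genes, 16 were tested, 8 rose and 1 fell, with the same counts adjusted over the list alone. Members below the filter included Ryr2 (5 and 3 reads in OECtrl, 8 and 10 in OENr4a3) and Pln (0 and 5, 1 and 3). The list passed camera (median log2 fold change 0.40, adjusted p = 0.0231; adjusted p = 0.599 with an estimated correlation). Slc8a1, the sodium-calcium exchanger, rose from 66.1 ± 8.07 to 157.7 ± 4.8 CPM (log2 fold change 1.26, adjusted p = 0.000247), Gja1, the gap junction protein connexin 43, from 58.7 ± 3.17 to 123.9 ± 1.43 CPM (1.08, adjusted p = 0.000298), and Cacna2d1, a calcium channel subunit, from 86.0 ± 6.54 to 149.5 ± 2.82 CPM (0.80, adjusted p = 0.00152). Casq2, the calcium-binding calsequestrin of cardiac muscle and named after its value was seen, was the member that fell (-0.85, adjusted p = 0.0192). The tested members had a median exonic length of 7716.5 bases, and longer genes were higher in OENr4a3 as a whole. With that length trend removed, a test chosen after seeing the data, the median was 0.33, 7 members rose and 2 fell, and the adjusted p was 0.0674, with Slc8a1 at 0.77 and Cacna2d1 at 0.44. The call of the list was also lost without OECtrl replicate 2 (0.0959) and without the filter on low counts (0.2).

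Of 20 cardiac transcription factors and natriuretic peptides, 14 were tested, and Nkx2-5 was among those below the filter (3 and 4 reads in OECtrl, 2 and 1 in OENr4a3). Of the 14, 3 rose and none fell, with 1 rise adjusted over the list alone (median log2 fold change 0.19, camera adjusted p = 0.256). These were Tbx20 (1036 ± 48.1 to 1378 ± 8.67 CPM, log2 fold change 0.41, adjusted p = 0.0124), Mef2a (0.33, adjusted p = 0.0429) and Prox1 (0.81, adjusted p = 0.0486). Without OENr4a3 replicate 1 or 2 the calls of Tbx20 (adjusted p = 0.231 and 0.21), Mef2a (0.358 and 0.448) and Prox1 (0.0915 and 0.378) were lost, as was that of Prox1 without OECtrl replicate 2 (0.117), in DESeq2 (0.133) and in limma-voom (0.055). The calls of Mef2a and Prox1 were lost too with upper-quartile factors (adjusted p = 0.0632 and 0.0564) and without the filter on low counts (0.0753 and 0.0783). Removing the length trend also ended these calls and left none of the list higher and 1 lower, at log2 fold changes of 0.07 for Tbx20, -0.08 for Mef2a and 0.59 for Prox1.

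Genes linked to senescence moved both ways, and neither list of them passed its test. Of 31 p53 targets and cell cycle inhibitors, 3 rose and 6 fell (4 and 6 adjusted over the list alone), and the list did not pass camera (median log2 fold change -0.07, adjusted p = 0.731). Once the trend with length was removed, 5 rose and 1 fell, and the list did not pass camera either (adjusted p = 0.821). Cdkn2a, which encodes the cell cycle inhibitors of the INK4A/ARF locus, fell from 35.3 ± 9.53 to 12.5 ± 0.245 CPM (log2 fold change -1.51 ± 0.185 SE, adjusted p = 0.0011). Cdkn2b, picked after its value was seen, fell as well (-0.58, adjusted p = 0.0265), and its call was lost in 5 of 13 alternative fits. Both genes are short, with 1172 and 1390 exonic bases, and short genes were lower in OENr4a3 as a whole. Cdkn2a kept its call in the 13 fits, at log2 fold changes from -1.755 to -1.165. It was the 1 member lower with the length trend removed, so the call of Cdkn2b ended there. Pml, a nuclear body protein, rose from 27.9 ± 3.32 to 47.6 ± 0.297 CPM (0.77, adjusted p = 0.00422), as did the receptor Eda2r (0.48, adjusted p = 0.0122) and, named after its value was seen, Trp53inp1 (0.34, adjusted p = 0.0303). Cdkn1a, a main p53 target also picked after its value was seen, measured 489.1 ± 34 and 466.9 ± 15 CPM (log2 fold change -0.07, 95% interval -0.282 to 0.147, adjusted p = 0.637), but passed as lower without OECtrl replicate 1 (adjusted p = 0.018). The calls of Eda2r (adjusted p = 0.173 and 0.174) and Trp53inp1 (0.405 and 0.334) were lost without OENr4a3 replicate 1 or 2, and that of Trp53inp1 also with the length trend removed (0.21, adjusted p = 0.0817) and without the filter on low counts (0.0549). Cdkn1a stood at 0.01 without OECtrl replicate 2.

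Of 54 senescence-associated secretory factors, 44 were tested, 11 rose and 14 fell (15 and 16 adjusted over the list alone), and the list did not pass camera (median log2 fold change -0.02, adjusted p = 0.753). With the length trend removed, 14 rose and 9 fell (18 and 12 adjusted over the list alone; camera adjusted p = 0.932), so which direction held more genes depended on that trend. Besides Igfbp4, the cytokine osteopontin encoded by Spp1 fell from 805.3 ± 23.7 to 328.1 ± 4.23 CPM (log2 fold change -1.29 ± 0.0904 SE, adjusted p = 5.41e-05) and Igfbp2 from 194.8 ± 21.5 to 64.4 ± 1.79 CPM (-1.60 ± 0.113 SE, adjusted p = 5.92e-05). Of members picked after their values were seen, Igfbp6 (-1.93, adjusted p = 0.000446), the collagenase Mmp13 (-1.97, adjusted p = 0.000946) and the urokinase receptor Plaur (-1.27, adjusted p = 0.00129) fell, and Igfbp5 rose from 6.59 to 32.0 CPM (2.30, adjusted p = 0.00134). Also picked after their values were seen, Vegfa (0.68, adjusted p = 0.00226) and Cxcl1 (2.33, adjusted p = 0.0137) rose and Il6 (-0.46, adjusted p = 0.0361) fell. Their calls were lost in 1, 1 and 5 of 13 alternative fits. The calls of the other genes named here were kept when any single library was left out.

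Genes of cell division were lower as groups, though only part of their members passed the gene test. Of 30 mitotic cell cycle genes, none rose and 15 fell (22 adjusted over the list alone), and the list passed camera (median log2 fold change -0.57, adjusted p = 4.26e-07; adjusted p = 0.599 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, fell from 33.9 ± 1.64 to 19.7 ± 1.27 CPM (log2 fold change -0.78, adjusted p = 0.00415), cyclin A from Ccna2 from 21.1 ± 1.01 to 12.1 ± 0.281 CPM (-0.80, adjusted p = 0.0052) and survivin from Birc5 from 13.1 ± 1.79 to 6.67 ± 0.165 CPM (-0.98, adjusted p = 0.00597). Of 30 DNA replication genes, none rose and 12 fell (15 adjusted over the list alone; median log2 fold change -0.40, camera adjusted p = 6.86e-07; adjusted p = 0.599 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 31.7 ± 3.3 to 18.8 ± 0.328 CPM (-0.75, adjusted p = 0.00597). Chaf1b (-0.83, adjusted p = 0.00953) and Rfc4 (-0.89, adjusted p = 0.0103) fell as well, and their calls were lost without OENr4a3 replicate 1 (Chaf1b, adjusted p = 0.0699) or replicate 2 (Rfc4, adjusted p = 0.0535). Rfc4 stood at -0.60 with the length trend removed and at -0.55 with GC content also removed.

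Of 32 fibroblast extracellular matrix genes, 12 rose and 4 fell (15 and 7 adjusted over the list alone), and the list did not pass camera (median log2 fold change 0.20, adjusted p = 0.256). After removal of the length trend, 8 rose and 6 fell (median 0.03, camera adjusted p = 0.75). The fibril-associated collagen Col12a1 rose from 216.9 ± 62.7 to 660.9 ± 17.2 CPM (log2 fold change 1.61, adjusted p = 0.000431), the matrix protein Fbln1 from 81.3 ± 3.87 to 134.2 ± 10.8 CPM (0.72, adjusted p = 0.00305) and the fibroblast receptor Pdgfra from 107.9 ± 20.7 to 200.2 ± 9.63 CPM (0.89, adjusted p = 0.00308). The members that fell, named after their values were seen, were Thy1 (-0.61), Lum (-0.40), Tcf21 (-0.37) and Lox (-0.34). Their calls were lost without OENr4a3 replicate 1 (adjusted p = 0.0555, 0.31, 0.462 and 0.206) and without replicate 2 (0.0944, 0.26, 0.217 and 0.421), and those of Lum (-0.22, adjusted p = 0.0628) and Tcf21 (-0.18, adjusted p = 0.158) with the length trend removed. The tested members of this list had a median exonic length of 6466.5 bases.

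**Figure D2:**
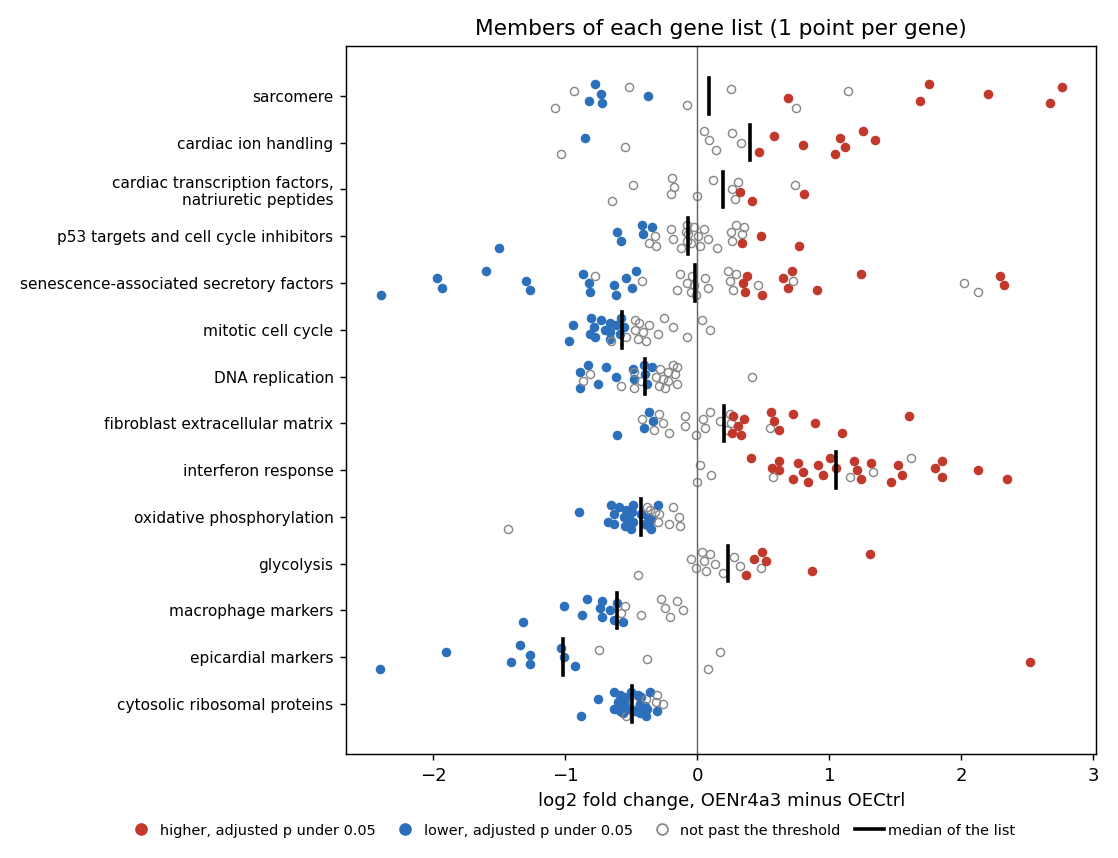
Log2 fold change, OENr4a3 minus OECtrl, of each tested member of the 8 study lists and of the 6 other lists that passed camera; filled points passed the gene test and a bar marks each list's median. Interferon response genes lie to the right (median 1.05), whereas mitotic genes (-0.57) and epicardial markers (-1.02) lie to the left, and secretory factors spread on both sides.

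Of the 17 other lists, 6 passed camera and none of them did with an estimated correlation. Of 31 interferon response genes, 24 rose and none fell (28 and none adjusted over the list alone), with a median log2 fold change of 1.05 (camera adjusted p = 6.18e-14; adjusted p = 0.599 with an estimated correlation). Oasl2 rose from 9.57 ± 2.03 to 34.5 ± 2.34 CPM (log2 fold change 1.86, adjusted p = 0.000215) and Ifit1 from 11.5 ± 1.09 to 33.8 ± 3.83 CPM (1.55, adjusted p = 0.000282), both antiviral genes induced by interferon. Of 18 glycolysis genes, 6 rose and none fell (7 and 1 adjusted over the list alone; median 0.24, camera adjusted p = 0.0136; adjusted p = 0.599 with an estimated correlation). The lactate transporter gene Slc16a3 rose from 40.25 ± 4.17 to 99.95 ± 7.51 CPM (1.31, adjusted p = 0.000235) and Bnip3, a mitophagy receptor gene induced by low oxygen, from 66.6 ± 12.7 to 121.8 ± 18.3 CPM (0.87, adjusted p = 0.00606). The call of the glycolysis list was lost without OECtrl replicate 1 (adjusted p = 0.188) or OENr4a3 replicate 1 (0.147).

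Many cytosolic ribosomal protein and oxidative phosphorylation genes fell by small amounts. Of 30 cytosolic ribosomal protein genes, 24 fell and none rose (26 and none adjusted over the list alone; median -0.49, camera adjusted p = 1.01e-07; adjusted p = 0.599 with an estimated correlation), among them Rps16 (-0.76, adjusted p = 0.00912) and Rps27a (-0.88, adjusted p = 0.00971). Of 31 oxidative phosphorylation genes, 21 fell and none rose (28 and none adjusted over the list alone; median -0.43, camera adjusted p = 2.58e-07; adjusted p = 0.599 with an estimated correlation), among them Ndufa4 (-0.89, adjusted p = 0.00368) and Cox5a (-0.68, adjusted p = 0.00662). The calls of Rps16 (adjusted p = 0.0879 without OENr4a3 replicate 1), Rps27a (0.0813 without replicate 2) and Cox5a (0.0596 without replicate 2) were lost when that library was left out. Ribosomal protein genes have many processed pseudogenes, and Rps16 stood at only 26.7 CPM in OECtrl, so their levels are uncertain. Both lists are made of short genes, with median exonic lengths of 2254 and 2154 bases. With the length trend removed, 13 and 12 of their members fell, with Rps16 at -0.43, Ndufa4 at -0.58 and Cox5a at -0.46 (-0.40 with GC content also removed).

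Gene length moved with the groups. Across the 15029 tested genes, the log2 fold change rose with exonic length (Spearman rho 0.42, across genes, which are not independent replicates). Of the shortest 10% of genes, 57 to 1278 bases long, 2.06% were called higher and 24.6% lower in OENr4a3 (median log2 fold change -0.42). Of the longest 10%, from 9607 bases, 40% were called higher and 2.46% lower (median 0.35). The OECtrl libraries also differed from each other by length (rho 0.356 for replicate 1 minus replicate 2), and the OENr4a3 libraries less so (-0.039). With the trend removed, 3048 genes were called, 2209 of them among the 3457 and in the same direction. The 18S ribosomal RNA gene Rn18s took 0.723% and 0.676% of counts in OECtrl and 0.247% and 0.205% in OENr4a3.

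**Figure D3:**
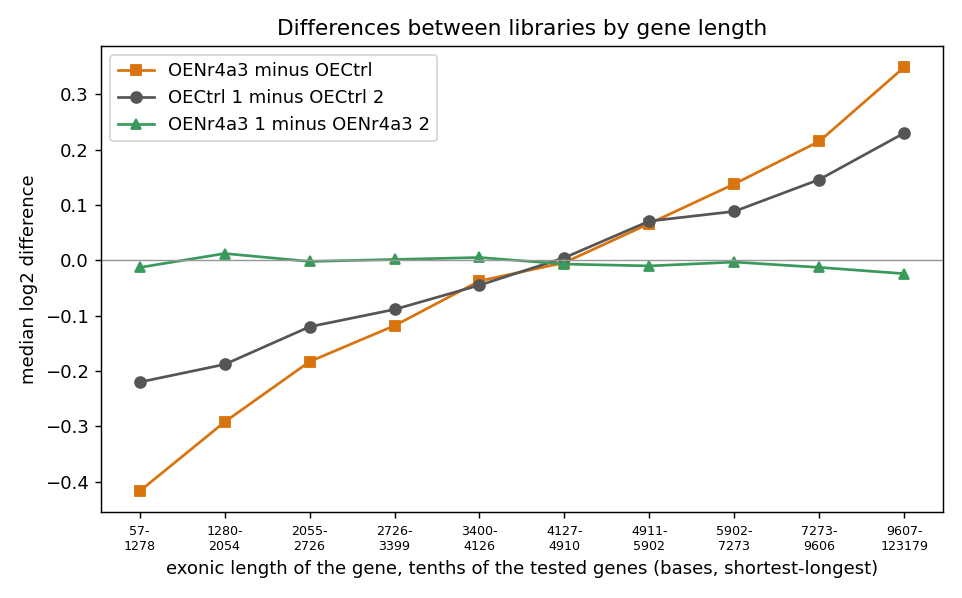
Median log2 difference in each 10% of the tested genes by exonic length in bases, for OENr4a3 minus OECtrl (squares), OECtrl 1 minus OECtrl 2 (circles) and OENr4a3 1 minus OENr4a3 2 (triangles). The group difference goes from -0.42 in the shortest 10% to 0.35 in the longest, the OECtrl pair from -0.22 to 0.23, and the OENr4a3 pair stays within 0.0241 of 0.

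Markers of other cells of the heart also differed. Of 19 macrophage markers, 11 fell and none rose (13 and none adjusted over the list alone; median log2 fold change -0.61, camera adjusted p = 6.96e-07; adjusted p = 0.599 with an estimated correlation). Lyz2, lysozyme of phagocytes, fell from 810.7 ± 5.95 to 522.4 ± 11.7 CPM (-0.63, adjusted p = 0.00212; 0.0576 without OENr4a3 replicate 2) and Fcer1g from 10.99 ± 1.46 to 4.40 ± 0.227 CPM (-1.32, adjusted p = 0.00227). Of 14 epicardial markers, which label the outer layer of the heart, 9 fell and 1 rose, with the same counts adjusted over the list alone (median -1.02, camera adjusted p = 0.000648; adjusted p = 0.599 with an estimated correlation). Upk1b fell from 338.3 ± 48.7 to 140.6 ± 13 CPM (-1.27, adjusted p = 0.000324) and Gpm6a from 206.3 ± 22.1 to 81.2 ± 0.523 CPM (-1.35, adjusted p = 0.000152), whereas Aldh1a2, the retinoic acid-synthesising enzyme, rose from 36.3 ± 1.57 to 208.4 ± 4.02 CPM (2.52, adjusted p = 2.48e-06). Smooth muscle and pericyte markers (4 of 14 higher, 4 lower) and endothelial markers (1 of 17 higher, 2 lower) did not pass camera (adjusted p = 0.784 and 0.354). The most abundant of these were Acta2, which fell from 2159 ± 56 to 1581 ± 23.7 CPM (-0.45, adjusted p = 0.00769; 0.189 and 0.154 without OENr4a3 replicate 1 or 2), and Flt1, which rose from 58.7 ± 6.12 to 113 ± 2.49 CPM (0.95, adjusted p = 0.000919). After removal of the length trend, 8 macrophage markers were called lower. Lyz2 then stood at -0.33, Acta2 at -0.24 and Flt1 at 0.57.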

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

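The tests with the length trend removed, alone or with GC content, were chosen after the results were seen; the others were planned. Of 55 named genes, 40 stayed on their side of the threshold under all alternatives, and 12 of the 49 called lost the call or turned under at least 1; of 52 genes picked later, 51 were called, and 33 of the 51 lost the call when a library was left out. Nr4a3 stayed between 6.14 and 6.57 on the log2 scale. Mef2a turned to -0.07925 with the length trend removed and -0.0229 with GC content also removed; its adjusted p ranged from 1.65e-10 to 0.857 over the alternatives. Genes higher and lower numbered 1121 and 757 without the filter on low counts, where more genes were tested; 452 and 351 with a 2-fold minimum; and 552 and 359 at an adjusted p under 0.01. Leaving out a library gave from 751 to 3942 higher and from 478 to 3831 lower genes. Without OENr4a3 replicate 1 they were 820 and 493, without replicate 2 751 and 478, without OECtrl replicate 1 3942 and 3831; the cause was not tested. Upper-quartile factors put 43.9% of calls higher, against 52.1%. The cardiac ion handling list had an adjusted p of 0.2 without the filter, 0.0674 with the length trend removed and 0.0641 with GC content also removed; leaving out a library gave 0.0184 to 0.0959, the highest without OECtrl replicate 2; the cause was not tested. With an estimated correlation the ion handling, mitotic and DNA replication lists had an adjusted p of 0.599, and with fry, which asks only whether a list's genes move 1 way, 0.127, 0.127 and 0.0697. Both tests called 0 of the other lists, against 6. Of 14 lists followed, 12 stayed on their side of the threshold under the remaining alternatives, the exceptions being ion handling and glycolysis. The labels do not say whether equal replicate numbers mark a shared culture or day. Deviations of same-numbered libraries correlated at -0.0776 (Pearson r, 15029 genes), which does not exclude a small shared effect. A replicate block gave 2021 higher and 1830 lower genes. It ended the calls of Mef2a (adjusted p = 0.0792) and, among genes picked later, of Trp53inp1 (0.0624), Skil (0.0646) and Fosl2 (0.0704). Depth limits members such as Tbx5 and Alas2, below 3 CPM.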

Other observations

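The enrichment of Gene Ontology terms, the removal of the length trend, the counts of genes seen in a single group, the quartiles of the ion handling list, the ratio of liver genes between the OECtrl libraries and the choice of genes named here without a prior rule came after the results were seen. Called genes were tested against the 9690 tested genes that carry a term, over 1157 terms and in each direction. Among the 1301 higher genes, 34 terms were enriched. Homophilic cell adhesion led (24 genes, 8.73 by chance, adjusted p = 0.00104), with 14 heart looping genes (4.16 by chance, adjusted p = 0.00474) and 33 genes of the response to hypoxia (17.5 by chance, adjusted p = 0.0166). Among the 1159 lower genes, 29 terms were enriched, led by translation (56 genes, 14.4 by chance, adjusted p = 2.8e-18) and the electron transport chain (37, 9.21 by chance, adjusted p = 2.77e-12), and protein folding was also among them (30, 9.09 by chance, adjusted p = 1.86e-07). With the length trend removed, 23 and 17 terms were enriched, led by the cellular response to interferon-beta among higher genes (13, 2.19 by chance, adjusted p = 1.67e-05) and by anaphase-promoting complex-dependent protein catabolism among lower genes (15, 2.76 by chance, adjusted p = 1.32e-06). Defense response to virus was also among the higher terms (24, 7.6 by chance, adjusted p = 9.22e-05). Homophilic adhesion (19, 6.77 by chance, adjusted p = 0.00407), hypoxia (34, 13.5 by chance, adjusted p = 0.000101), translation (40, 15.1 by chance, adjusted p = 1.32e-06), the electron transport chain (21, 9.66 by chance, adjusted p = 0.0272) and protein folding (26, 9.54 by chance, adjusted p = 0.000191) were still enriched, and heart looping was not. Cell cycle arrest was enriched among higher genes (21, 9.53 by chance, adjusted p = 0.0218). It still was with the trend removed (17, 7.39 by chance, adjusted p = 0.0436). Mitotic nuclear division was enriched among lower genes (36, 20.5 by chance, adjusted p = 0.0219), but not with the trend removed. Positive regulation of cell division was enriched among higher genes only with the trend removed (10, 3.02 by chance, adjusted p = 0.0372).

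Several lists that did not pass camera held single genes with large changes. Sod3, the extracellular superoxide dismutase, rose from 155.1 to 612 CPM (log2 fold change 1.98, adjusted p = 1.06e-05) while 6 of the other antioxidant genes fell (list adjusted p = 0.256). Itga8 (1.49, adjusted p = 0.000165), Cspg4 (1.43, adjusted p = 0.00237) and Notch3 (0.96, adjusted p = 0.00261) rose among smooth muscle and pericyte markers, where the median (-0.22) and the mean (0.10) of the list differ in sign and the camera test pointed down. Cd36, a fatty acid carrier, rose (0.94, adjusted p = 0.00167) in a fatty acid oxidation list with 2 higher and 2 lower of 21 genes (adjusted p = 0.288). Myofibroblast and TGF-beta response genes included 6 that fell and 2 that rose of 21 (median -0.19, adjusted p = 0.256). NF-kB response genes included 3 higher and 2 lower of 23 (adjusted p = 0.256), immediate early genes 1 and 3 of 20 (adjusted p = 0.256), unfolded protein response genes 1 and 1 of 18 (adjusted p = 0.347) and mitochondrially encoded genes 1 and 3 of 13 (adjusted p = 0.418). With the length trend removed, 6 mitochondrially encoded genes were higher and 1 lower, and the list median went from -0.027 to 0.308 (adjusted p = 0.334). None of 2 Schwann cell markers (adjusted p = 0.791) and the single erythroid gene tested, Alas2 (adjusted p = 0.514), was called. Alas2 passed only without OECtrl replicate 1 (adjusted p = 0.0079).

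Both OECtrl libraries held more liver transcripts than OENr4a3, where some, such as Trf (429 and 412 reads) and Hpx (39 and 19), were still present. Of 28 liver genes not looked at beforehand, 75% were at least 4 times higher in each OECtrl than in each OENr4a3 library. Alb, looked at beforehand, had 453 and 345 reads against 1 and 0. The 75% lies between the bounds set for and against liver RNA or reads in the OECtrl libraries. Such a source in both OECtrl libraries may be present. The score cannot tell it from a change in the fibroblasts, since either could make these genes higher in OECtrl. Had a single source fed both, their ratio would be constant if nothing else set the libraries apart. Of 27 intervals 81.5% held the pooled share, with 5 outside where 1.35 would lie outside by chance. These intervals cover counting error only, while the OECtrl pair differed beyond sampling noise and by gene length (rho 0.356). The score therefore cannot decide, and a single source stays open too. The list goes beyond liver: 35 genes had at least 10 reads in each OECtrl and at most 1 in each OENr4a3 library, 20 of them on the liver list, against 16 genes the other way. Others of the 35 were the immunoglobulin genes Igkc (23 and 31 reads against 0 and 1), Ighg1 (16 and 36 against 0 and 0) and Jchain (25 and 36 against 1 and 0). A heart fibroblast is not known to express them, so for these genes the reads argue against a change in the fibroblasts. Afp, abundant in fetal and newborn liver, had only 11 and 10 reads. A biological explanation through Nr4a3 was not tested.

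Short genes were lower and long genes higher in OENr4a3. A length-dependent yield that varies between libraries whatever their group is a candidate explanation, since the OECtrl pair, alike in treatment, differed by length too (rho 0.356); an effect of Nr4a3 on top of it stays open, as the group and the libraries are confounded. With the trend removed the list still passed camera for interferon response (median log2 fold change 1.13), mitotic cell cycle (-0.58), DNA replication (-0.387) and epicardial markers (-1). Macrophage markers (-0.375), ribosomal proteins (-0.273), oxidative phosphorylation (-0.271) and glycolysis (0.168) also still passed. Apart from macrophage markers, ribosomal proteins and oxidative phosphorylation, this argues against exonic length as the only cause of these calls. With an estimated correlation, where the test had little power, none of these lists passed (adjusted p = 0.727 for glycolysis and 0.658 for the others). The medians of the macrophage marker, ribosomal protein and oxidative phosphorylation lists had been -0.611, -0.492 and -0.43 before. Their median exonic lengths were 1732, 2254 and 2154 bases. The deposited exonic length need not be that of the transcripts present, so for these lists length is not excluded as the cause of the rest. For cardiac ion handling the median went from 0.398 (quartiles 0.0804 and 1.05) to 0.327 (0.0715 and 0.706) and the mean from 0.383 to 0.2, and the call ended (adjusted p = 0.0674); length as its whole cause cannot be told apart from a rise of these genes.

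As lists, macrophage and epicardial markers were lower in OENr4a3, with 11 of 19 and 9 of 14 called lower and Aldh1a2 higher. With the length trend removed, 8 of 19 and 10 of 14 were called lower. If the share of a cell type fell, its markers would fall alike, and with the length trend removed 84.2% of 19 macrophage markers had intervals that held the list's median, between the bounds set for and against, so fewer macrophages may account for their fall and this cannot be told apart from a change within them. For epicardial cells 50% of 14 markers did, among them Bnc1 (-0.947), Upk3b (-0.962), Upk1b (-1.04) and Msln (-1.15). Of the others, Krt8 fell by 2.15 while Wt1 stood at 0.05 and Aldh1a2 at 2.72. This argues against a lower share as the whole explanation only if other cells in the culture do not make these markers, which was not tested. A response of these cells to Nr4a3 was not tested.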
